A study of Mus musculus with 20 samples.

How the data were processed

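ATAC-seq was performed on nuclei of FACS-sorted mouse cells with a Nextera transposase, and paired-end libraries were sequenced on an Illumina HiSeq instrument, per the labels' protocols. The submitters' processing notes name FastQC, Bowtie 0.12.8, SAMtools 1.3.1, MACS2 2.1.1, bedtools 2.20.1 and SICER, and the mm9 genome build, with no role or order. How duplicates, mitochondrial reads, repeats and the offset of Tn5 cuts were treated is not given in the sources used here. These choices set which peaks exist, and peaks in repeats or on the mitochondrial chromosome may have been kept.

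The 14 deposited lists hold 3 kinds of values. For each normal cell type, the authors called peaks on both samples together at a q-value of 0.001, as the list names and sample descriptions state. The value of each of these peaks is a fold, the ratio of enrichment the authors' peak caller gave over its own background. It was used only to rank, filter or describe peaks within a list. For each normal cell type there is also a UAR and a URR list, and for luminal PY230 cells a list of regions open and a list of regions closed in SOX10-high cells. Each region in these 10 lists carries a score deposited by the authors. Its scale is not given in the sources used here, and some scores are written as infinite. Region edges of these 10 lists lie on a 100 bp grid. The UAR and URR lists are attached to single samples but named for a cell type, so they were treated as lists of that cell type. How they were called is not given in the sources used here. The sample descriptions name the open PY230 list with the luminal SOX10-high samples and the closed list with the luminal SOX10-low samples, so the lists were read as a comparison of these groups. Whether other libraries entered it is not given in the sources used here. No counts, signal tracks or values per sample were used, so depth per sample is unknown, no replicate error can be given and no sample could be left out. Tests over regions compare deposited lists, not animals or tumours. None of the 14 lists was named for basal SOX10-high PY230 cells, C3-1-TAg tumours, bulk tumour or culture, so these samples were not analysed here.

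Coordinates are mm9 and 1-based. Peak lists were kept as deposited, since their mitochondrial peaks reach from the first to the last base of that chromosome, and the grid-based lists were moved by 1 base. Mitochondrial peaks were left out of all comparisons, which used 19 autosomes and X. The only annotation at hand was of another mouse build, and coordinates were not converted. The 12 gene lists and 13 motifs fixed beforehand were therefore not tested, regions are given by position, and no gene is named.

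Overlap means at least 1 shared bp. Jaccard indices, shares and their differences have standard errors from a jackknife that leaves out each of 20 chromosomes, and chance overlap was measured with 200 circular shifts of at least 1 Mb. Shares have exact (Clopper-Pearson) 95% binomial intervals. A share of 0 is given with the limit that 3 counts would set. Open and closed PY230 lists were compared with Fisher's exact test (two-sided), with Benjamini-Hochberg adjustment over 4 peak lists or 8 UAR and URR lists, and odds ratios are conditional estimates. The share on chromosome X was tested over 14 lists against the union of peaks. Which other type's peaks a UAR list shared most was tested with an exact McNemar test over regions. Clustering was measured as the share of regions with a neighbour within 10 kb and the largest number in 1 Mb. It was set against 1000 random draws from the cell type's peaks or from both PY230 lists, with adjustment over 10 lists. Tests of each chromosome against the others, the McNemar tests and the comparison of regions outside all normal peaks were added after the lists were seen.

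So were some alternatives and several tests of the closing section, which are named there. The other tests, the samples and the other alternatives were fixed before the data were examined, including the rule for the regions named: the 3 regions of highest fold or score in each list, and the 3 densest 1 Mb windows of each UAR and PY230 list. Equal values, such as infinite scores, were ordered by chromosome name and start. The text gives those that bear on a comparison. In the peak lists the strongest nuclear peak is added, because mitochondrial peaks take the first 2 places. Alternatives were an overlap of at least 50%, the 30015 strongest peaks of each list, peaks at or above the list's median fold, a fixed width of 500 bp, autosomes only, merging within 500 bp, other window and neighbour sizes, and PY230 regions inside normal peaks only. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. They were tested on simulated data. On simulated lists, overlap counts and the Jaccard index equalled those of bedtools 2.31.1. In 200 simulations each, lists of 3208 and 15108 regions were drawn independently at the rate of basal peaks in UARs (6157 of 80294). Fisher's test called 4.0% of comparisons with no planted difference and 100.0% at a planted ratio of 1.5. PY230 regions overlapped UARs at other shares, such as 1.37% and 1.39% for basal UARs, and lay in clusters. The simulations therefore do not give the power or error of the tests at those shares. The jackknife SE was 1.05 times the true SD for a share of 80294 peaks, and 1 of 40 random sets of 300 basal peaks was called clustered.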

Results

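The series profiled open chromatin by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into accessible DNA, in mouse mammary cells and mammary tumour cells. Of 20 samples, 8 were normal cells sorted from C57BL6J mammary glands, with 2 samples for each of 4 populations. These were the fMaSC population (fetal mammary stem cells) at embryonic day 18, and adult basal, luminal progenitor and mature luminal cells. Basal cells form the contractile outer layer of the gland, and mature luminal cells are hormone-sensing cells of its inner layer. The other 12 samples were mouse mammary tumour or cultured cells. PY230, a mouse mammary tumour line grown as transplants, gave 3 luminal SOX10-high samples, 3 luminal SOX10-low samples and 2 basal SOX10-high samples. It also gave 1 bulk tumour and 1 culture. Spontaneous C3-1-TAg tumours gave 2 basal SOX10-high samples. SOX10 is an HMG-box transcription factor of the neural crest. Results below rest on 14 region lists: 4 pooled peak lists, 8 lists of regions that set 1 normal type apart, and 2 lists of PY230 regions called open or closed in SOX10-high cells. The files hold no reads or counts, so the depth of each sample is unknown, and replicates cannot be compared because each list combines samples. Errors given as SE come from leaving out each of the 20 chromosomes in turn. They describe how even a value is along the genome, not how it varies between mice.

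The first comparison asked how much open chromatin each normal cell type had. Basal cells had the most accessible sequence, with 80294 nuclear peaks covering 70.4 Mb, against 79910 peaks and 48.1 Mb in fMaSC. Luminal progenitors had 60030 peaks over 47.5 Mb, and mature luminal cells 61584 peaks over 43.9 Mb. Peaks were broadest in basal cells, with a mean width of 877 ± 5.23 bp (SE over chromosomes), and narrowest in fMaSC, at 602 ± 3.18 bp. Mean widths were 791 ± 3.26 bp in luminal progenitors and 712 ± 4.73 bp in mature luminal cells. The authors' fold enrichment of a peak over its background had a median of 7.60 in fMaSC, 7.98 in basal cells, 6.86 in luminal progenitors and 8.47 in mature luminal cells. Each list held 3 mitochondrial peaks, 2 of which had the highest folds of that list. The strongest nuclear peak of fMaSC lay on chromosome 17 from 39979863 to 39985859 (mm9), with a fold of 81.3. The same site led the nuclear peaks of basal cells, with a fold of 73.7, and of mature luminal cells, with 87.9. Luminal progenitors had their strongest nuclear peak on chromosome 2 from 98506312 to 98507579, with a fold of 61.1. Both sites held a peak in every normal cell type, so neither sets a type apart. Peaks in repeats may have been kept, and whether these sites lie in repeats was not tested. Counts and widths of separately called lists move with sequencing depth, so they carry no test between cell types.

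The next comparison asked which cell types share accessible sites. Relative to what either list covered, luminal progenitor and mature luminal cells overlapped the most, with a Jaccard index (shared bases over all bases covered by either list) of 0.474 ± 0.00582. Basal and mature luminal cells had the lowest index, at 0.342 ± 0.00487, and basal cells and luminal progenitors lay between, at 0.449 ± 0.00504. The order depended on the measure. In shared bases, fMaSC with basal cells and basal cells with luminal progenitors led with 36.5 Mb each. They were followed by fMaSC with luminal progenitors (29.8 Mb) and the luminal pair (29.4 Mb). Basal with mature luminal cells shared 29.1 Mb and fMaSC with mature luminal cells 24.3 Mb. With merged regions in place of bases, a measure added after the data were seen, the index was highest for fMaSC with basal cells (0.497), followed by the luminal pair (0.471), and lowest for fMaSC with mature luminal cells (0.340). Of luminal progenitor peaks, 74.6% ± 0.518 overlapped a basal peak by at least 1 bp and 64.5% ± 0.903 a mature luminal peak. Of mature luminal peaks, 63.7% ± 0.529 overlapped a luminal progenitor peak and 61.5% ± 0.756 a basal peak. Among 200 random circular shifts of one list along each chromosome, the Jaccard index never exceeded 0.0126 for any of the 6 pairs. All 6 observed values were therefore far above chance placement, which ignores the grouping of peaks near genes.

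Fetal cells shared less accessible sequence with mature luminal cells than with basal cells or luminal progenitors. The Jaccard index of fMaSC was 0.446 ± 0.00270 with basal cells, 0.454 ± 0.00424 with luminal progenitors and 0.359 ± 0.00571 with mature luminal cells. The index with mature luminal cells was lower than that with luminal progenitors by 0.0954 (95% interval 0.0911 to 0.0998, jackknife over 20 chromosomes) and lower than that with basal cells by 0.0873 (0.0768 to 0.0978). These 2 differences kept their sign with equal numbers of peaks, with a fixed width and on autosomes alone. Basal minus luminal progenitor gave a difference of -0.00812 (-0.0153 to -0.000972). With the 30015 strongest peaks of each list it was -0.0334 ± 0.00371, in the same direction. The order turned over when all peaks were set to 500 bp, where the difference was 0.0199, and when regions rather than bases were counted, where it was 0.0476. Which of the 2 adult types stood closer to fMaSC was thus not settled by these lists.

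Merging all peaks gave 128797 union regions covering 100.6 Mb. Of these, 27947 regions, or 21.7%, had a peak in all 4 cell types. Another 59185 regions had a peak in 1 type alone: 19944 in basal cells, 17328 in fMaSC, 15777 in mature luminal cells and 6136 in luminal progenitors. Regions shared by all types were wide, with a median of 1332 bp, against 303 bp for fMaSC-only and 431 bp for basal-only regions. The most frequent pair was fMaSC with basal cells, at 12399 regions, compared with 4083 for the luminal progenitor and mature luminal pair and 2670 for fMaSC with luminal progenitors. The most frequent trio was fMaSC, basal and luminal progenitor, at 8330 regions. With the 30015 strongest peaks of each list, regions seen in 1 type alone numbered 8432 in mature luminal cells, 5940 in fMaSC, 5926 in basal cells and 4029 in luminal progenitors. The order among the first 3 of these types thus differed between all peaks and the strongest peaks.

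**Figure D1:**
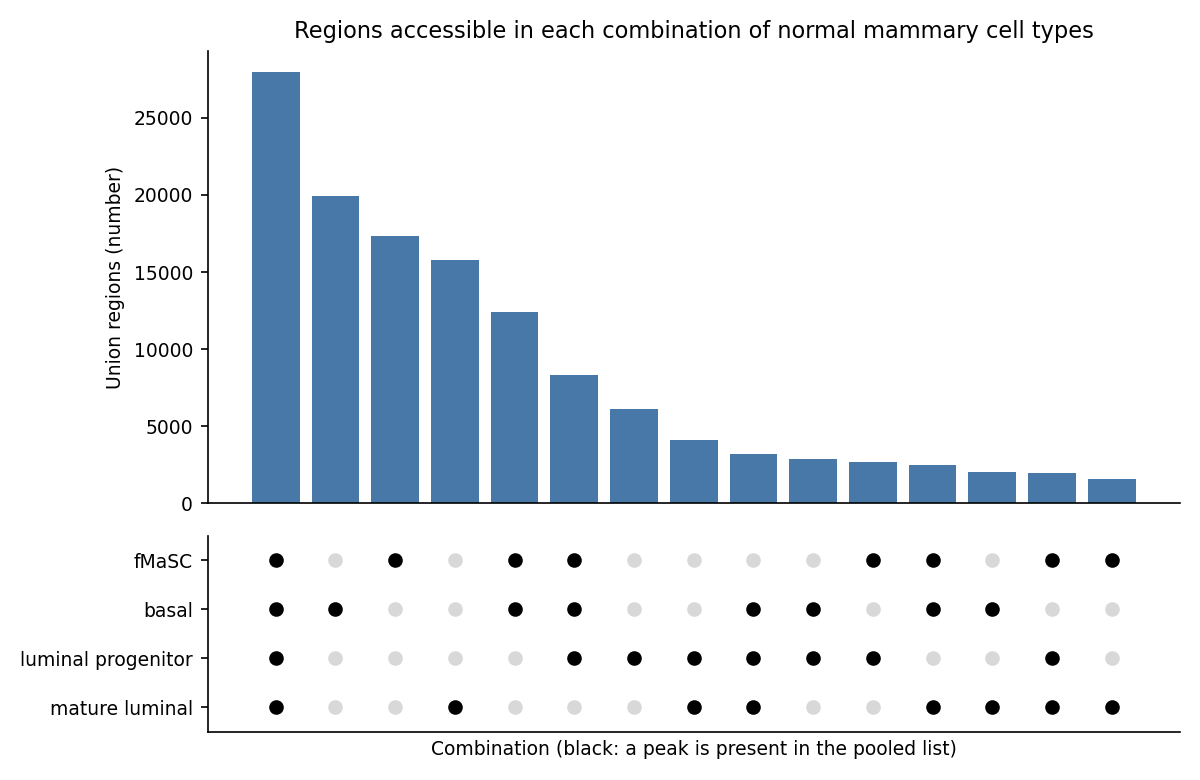
Number of merged union regions (bars, y axis) in each of the 15 combinations of cell types, marked by black dots below each bar. Regions open in all 4 types are the most frequent combination (27947), followed by regions open only in basal cells (19944), only in fMaSC (17328) and only in mature luminal cells (15777).

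Lists named UAR and URR for each normal cell type were then set against the peaks to learn what they hold. The labels do not expand these abbreviations. By the overlaps, UARs held peaks of their own type, and URRs held peaks of the other 3 types more often than of their own. All 1222 fMaSC UARs overlapped an fMaSC peak, as did 306 of 306 luminal progenitor UARs, 5142 of 5144 basal UARs and 3280 of 3282 mature luminal UARs with peaks of their own type. All 242 fMaSC URRs, 71 basal URRs and 27 luminal progenitor URRs overlapped peaks of each of the other 3 types, and 1025 of 1028 mature luminal URRs did. URRs were not free of peaks of their own type, which lay in 44.2% of fMaSC, 33.8% of basal, 51.9% of luminal progenitor and 20.6% of mature luminal URRs. Cell types differed in both directions. Basal cells had the most UARs (5144) and only 71 URRs. Mature luminal cells had both many UARs (3282) and the most URRs (1028). Fetal cells had 1222 UARs and 242 URRs, and luminal progenitors had the fewest of each, 306 and 27. Peaks inside UARs had a higher median fold than the other peaks of the same list, with no test made. It was 14.7 against 7.97 in mature luminal cells, 12.9 against 7.60 in fMaSC, 12.1 against 7.76 in basal cells and 10.8 against 6.86 in luminal progenitors.

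UARs were not empty of peaks in the other types. At least 1 other type had a peak in 49.2% of basal UARs (95% exact binomial interval 47.8 to 50.6%), 46.0% of mature luminal UARs (44.3 to 47.7%), 36.3% of luminal progenitor UARs (30.9 to 41.9%) and 26.3% of fMaSC UARs (23.8 to 28.8%). These peaks mostly covered less than 50% of the UAR, whether through their size or through overlap at an edge. When a peak had to cover at least 50% of the region, the shares fell to 3.58% for basal, 2.86% for mature luminal, 0.654% for luminal progenitor and 3.36% for fMaSC UARs. Among mature luminal UARs, 42.7% ± 1.09 overlapped a luminal progenitor peak and 18.6% ± 0.666 a basal peak. This difference was significant (exact McNemar test over regions, two-sided, adjusted p = 1.89e-177 over 4 lists) and remained so with 30015 peaks per list, at 13.3% against 1.92%. Basal UARs overlapped fMaSC peaks in 42.8% ± 1.05 and luminal progenitor peaks in 26.2% ± 0.570 of cases, but with the 30015 strongest peaks of each list the difference was 0.272 points (exact McNemar test, p = 0.585), and at 50% overlap it turned to -1.28 points (exact McNemar test, p = 3.53e-08). Luminal progenitor UARs overlapped fMaSC peaks in 27.8% ± 3.06 and mature luminal peaks in 19.3% ± 2.55 (exact McNemar test, adjusted p = 0.00173), against 2.61% and 3.59% with the strongest peaks (exact McNemar test, p = 0.549). For fMaSC UARs, 19.1% ± 1.32 overlapped a basal peak and 16.5% ± 1.18 a luminal progenitor peak (exact McNemar test, adjusted p = 0.0199), and with the strongest peaks the direction turned, to 1.55% and 4.66% (exact McNemar test, p = 2.57e-07). Regions within a list are not independent, so these p-values describe the lists rather than the cell populations.

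**Figure D2:**
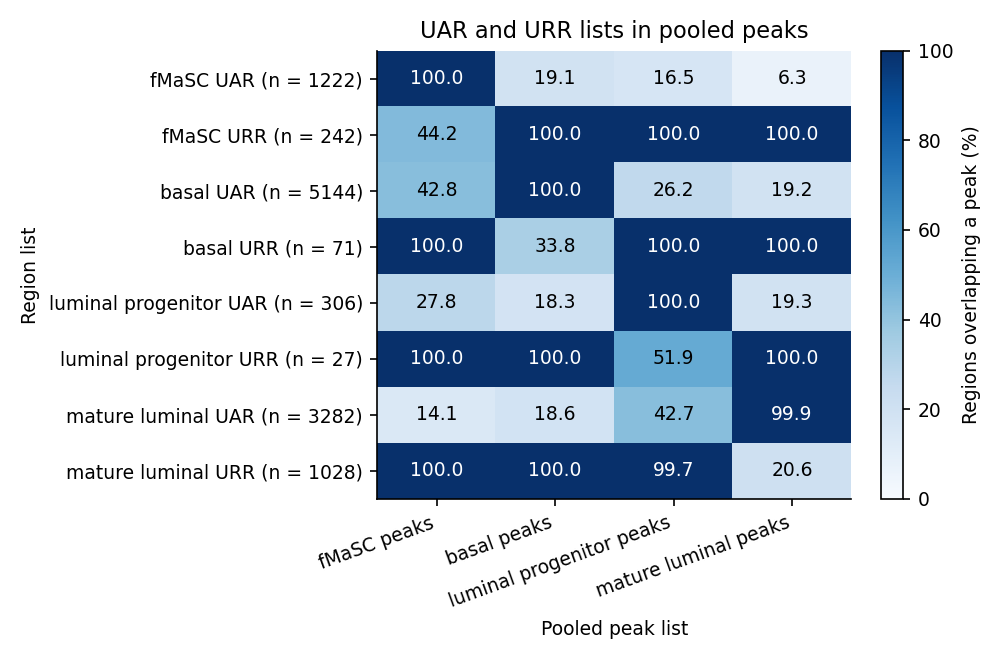
Share of regions (%, color scale and printed values) of each UAR and URR list (rows, with the number of regions) that overlap a peak of each normal cell type (columns) by at least 1 bp. UAR rows are near 100 only in their own cell type, and URR rows are near 100 in the other 3; mature luminal UARs reach 42.7 with luminal progenitor peaks.

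By score, the leading mature luminal UAR lay on chromosome 2 from 73931201 to 73932300, with a score of 72176, and overlapped luminal progenitor and mature luminal peaks. The leading fMaSC UAR, on chromosome 5 from 122146401 to 122147300, overlapped an fMaSC peak alone. So did the leading luminal progenitor UAR with its own type, on chromosome 5 from 39176501 to 39178200. Of the 19 basal UARs with an infinite score, the first 3 by position lay on chromosome 1 from 92324801 to 92326500 and from 134463301 to 134465300 and on chromosome 12 from 56107801 to 56110000, and each overlapped a basal peak alone. The densest 1 Mb windows of basal UARs began at 118836400 on chromosome 7 and at 75377450 on chromosome 11, with 22 UARs each, against a median of 16 in the densest window of 1000 random draws of basal peaks (adjusted permutation p = 0.0167). For mature luminal UARs the densest window began at 35091650 on chromosome 8 and held 13, against a median of 12 in draws (adjusted permutation p = 0.427). The densest windows of fMaSC and luminal progenitor UARs did not pass this test either (adjusted permutation p = 0.926 and 0.0899), although in windows of 500 kb luminal progenitor UARs did (adjusted permutation p = 0.015). Basal UARs lay close together, with 23.6% having another basal UAR within 10 kb, against a median of 10.7% in 1000 random draws of basal peaks (adjusted permutation p = 0.00143, resting on the smallest p the draws can give). The same share was 11.5% against 7.13% for mature luminal UARs and 5.23% against 0.654% for luminal progenitor UARs, both with the same adjusted p. For fMaSC UARs it was 3.68% against 2.29% (adjusted permutation p = 0.0262).

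The share of regions on chromosome X differed between lists, and 5 of 14 lists were below the union of peaks by test. The union merges the peaks of all 4 types, so the lists are not independent of it and the p-values are descriptive. Chromosome X carried 2.14% of union regions, 1.93% of basal peaks (adjusted p = 0.00366, Fisher's exact test) and 0.622% of basal UARs (32 of 5144, Fisher's exact test against the union, two-sided, adjusted p = 9.06e-17 over 14 lists). Mature luminal UARs (1.28%, adjusted p = 0.00155, Fisher's exact test) and mature luminal URRs (0.584%, adjusted p = 0.000553, Fisher's exact test) were also below the union, as were closed PY230 regions (1.52%, adjusted p = 1.01e-06, Fisher's exact test). The other 9 lists were not distinguishable from the union. They included fMaSC UARs at 1.80% (exact interval 1.13 to 2.71%), luminal progenitor UARs at 0.980% (0.203 to 2.84%) and open PY230 regions at 1.75% (1.32 to 2.26%). The URRs of fMaSC (3.31%), basal cells (2.82%) and luminal progenitors (3.70%) had higher shares that rested on 8, 2 and 1 regions.

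The tumour comparison asked which sites gain or lose accessibility in luminal PY230 cells with high SOX10. Far more regions were closed than open in SOX10-high cells, with 15108 closed and 3208 open regions, a ratio of 4.71, and no region was in both lists. The depth of the compared samples is unknown, so this ratio may reflect the libraries as well as the cells and carries no test. Most closed regions overlapped sites that normal mature luminal cells keep open. A mature luminal peak was present in 83.1% of closed regions (± 0.473, SE over chromosomes) and in 7.29% (± 0.437) of open regions. The odds of holding a mature luminal peak were 62.5 times higher in the closed list (95% interval 54.3 to 72.2, Fisher's exact test, with a p too small to represent). Open regions instead held fMaSC peaks in 43.6% ± 1.29, against 25.6% ± 0.626 of closed regions, with an odds ratio of 2.24 (2.07 to 2.43, Fisher's exact test, two-sided, adjusted p = 1.15e-86). They held luminal progenitor peaks in 48.7% ± 1.47, against 31.4% ± 0.705, with an odds ratio of 2.07 (1.91 to 2.23, Fisher's exact test, adjusted p = 1.37e-74). Basal peaks were present in 29.2% ± 1.54 of open and 30.1% ± 0.963 of closed regions, a difference of -0.824 points that did not pass the test (Fisher's exact test, adjusted p = 0.361). With all regions set to 500 bp, which removes the greater width of open regions (median 1400 bp against 1100 bp), basal peaks were less frequent in open regions by 2.18 points (Fisher's exact test, adjusted p = 0.0126). The odds ratios compare with a closed list in which 83.1% of regions held a mature luminal peak, not with normal sites in general. Among all union regions, 1.88% lay in the open list. It held 2.18% of fMaSC-only, 9.66% of luminal-progenitor-only and 0.717% of basal-only regions.

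UARs and URRs gave a sharper picture of the same lists. Of 3282 mature luminal UARs, 2728 (83.1%, exact interval 81.8 to 84.4%) were closed in SOX10-high cells and 1 was open. Luminal progenitor regions moved the other way. Of 306 luminal progenitor UARs, 91 (29.7%, 24.7 to 35.2%) were open and 1 was closed, while 20 of the 27 luminal progenitor URRs (74.1%, 53.7 to 88.9%) were closed and 0 were open, which allows a share of up to 11.1%. Mature luminal URRs, which normal mature luminal cells hold less accessible than the other types, were open in 114 of 1028 cases (11.1%, 9.23 to 13.2%) and closed in 2. Fetal UARs were open in 93 of 1222 cases (7.61%, 6.19 to 9.24%) and closed in 9 (0.736%). Basal UARs were touched little, with 43 of 5144 (0.836%) open and 203 (3.95%) closed. Intervals and limits cover counting error only.

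As shares of the PY230 lists, 18.4% ± 0.394 of closed regions and 0.0312% of open regions overlapped a mature luminal UAR (Fisher's exact test, two-sided, adjusted p = 6.3e-252 over 8 lists). Luminal progenitor UARs were overlapped by 2.93% ± 0.262 of open and 0.00662% of closed regions (odds ratio 456, interval 79.8 to 18202, Fisher's exact test, adjusted p = 5.12e-70). For fMaSC UARs the shares were 2.90% ± 0.240 and 0.0596% (odds ratio 50.1, 25.2 to 113, Fisher's exact test, adjusted p = 1.23e-59). For mature luminal URRs they were 3.58% ± 0.352 and 0.0132% (odds ratio 281, 75.9 to 2347, Fisher's exact test, adjusted p = 3.33e-84). These odds ratios too compare with a closed list in which 83.1% of regions held a mature luminal peak. Such peaks lay in 19.3% of luminal progenitor UARs, 6.30% of fMaSC UARs and 20.6% of mature luminal URRs. The low closed shares therefore partly follow from how the lists are composed. Basal UARs were overlapped by 1.37% ± 0.331 of open and 1.39% ± 0.150 of closed regions, with an odds ratio of 0.987 (0.694 to 1.37) and an adjusted p of 1 by Fisher's exact test. Without the 7 chromosomes described below, on which open regions were in surplus, that difference became -0.764 points (Fisher's exact test, adjusted p = 0.0296). The URRs of fMaSC and of luminal progenitors were more frequent in the closed list (Fisher's exact test, adjusted p = 0.0364 and 0.0483), with open minus closed differences of -0.194 and -0.132 points. Without those chromosomes, where fewer regions were tested, these were -0.177 and -0.173 points and no longer passed (Fisher's exact test, adjusted p = 0.278 and 0.208). For basal URRs, overlapped by 1 open and 8 closed regions, no difference was detectable.

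**Figure D3:**
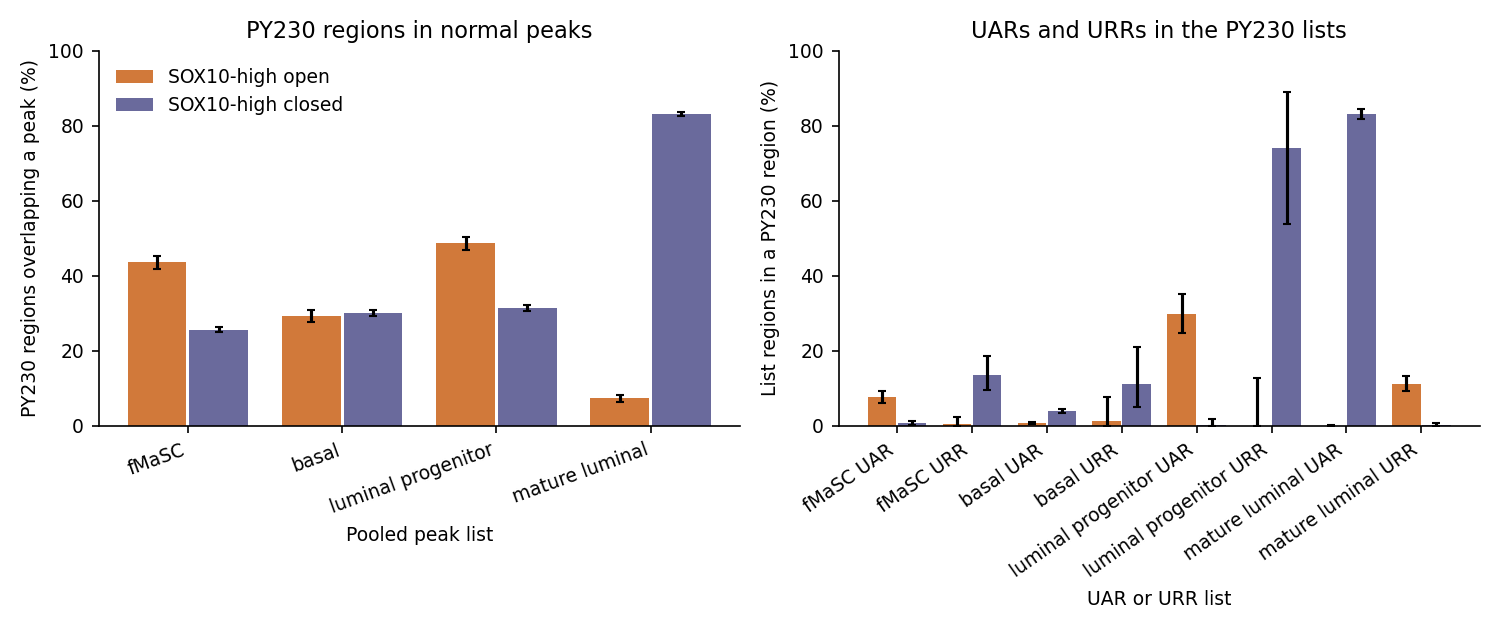
Left, share of PY230 regions (%) that overlap a pooled peak of each normal cell type; right, share of each UAR or URR list (%) that overlaps a PY230 region. Bars are orange for SOX10-high open and purple for SOX10-high closed, with 95% exact binomial intervals; mature luminal UARs reach 83.1% in the closed list and luminal progenitor UARs 29.7% in the open list.

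The combinations of cell types separated the lists further. Union regions open only in mature luminal cells were closed in SOX10-high cells in 42.8% of cases (6750 of 15777) and open in 0.158%. Union regions shared by the luminal progenitor and mature luminal types were closed in 36.9%. All 8 combinations that included mature luminal cells had closed shares of at least 7.33%, whereas all 7 combinations without them had closed shares of at most 2.06%. The highest open shares were in regions shared by fMaSC and luminal progenitors alone (12.1%, 324 of 2670) and in luminal-progenitor-only regions (9.66%, 593 of 6136). They were followed by fMaSC, basal and luminal progenitor regions (5.56%). Regions of fMaSC alone were open in 2.18% and of basal cells alone in 0.717%. The 3 open regions with the highest scores, on chromosome 7 from 93661701 to 93662500 and from 54028001 to 54029400 and on chromosome 5 from 130398701 to 130399500, overlapped no peak of any normal type. Of the 3 closed regions with infinite scores, those on chromosome 19 from 47587001 to 47590500 and on chromosome 1 from 177169201 to 177171000 were mature luminal UARs.

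Open regions were gathered along the genome. Another open region lay within 10 kb of 18.5% of them, against a median of 7.64% in 1000 random draws from both PY230 lists (adjusted permutation p = 0.00143). For closed regions the share was 34.5% against 29.8% (adjusted permutation p = 0.00143). Since most regions of both lists are closed, each draw was mostly the closed list. For closed regions the test therefore shows little beyond their separation from open regions. Draws did not keep the number of regions per chromosome, so differences between chromosomes can enter these results and those for windows. The densest 1 Mb windows of open regions began at 62083250 on chromosome 4, with 18 open regions, at 114108950 on chromosome 4, with 16, and at 78664050 on chromosome 15, with 15, where draws gave a median of 11 in the densest window (adjusted permutation p = 0.00999). These windows held 3, 2 and 3 closed regions. Closed regions were densest in windows beginning at 136797850 on chromosome 7 and at 118703900 on chromosome 14, with 40 each, and at 120864750 on chromosome 3, with 39, against a median of 36 in the densest window of draws (adjusted permutation p = 0.0167). Whole chromosomes differed as well. Open regions made up 17.5% of both lists together but 32.5% on chromosome 18 (exact interval 28.9 to 36.4%), 29.6% on chromosome 4 (27.1 to 32.2%) and 27.2% on chromosome 19 (23.3 to 31.3%). Chromosomes 1, 8, 13 and 15 were also above the rest (Fisher's exact test, adjusted p at most 0.000983 for the 7). These 7 chromosomes held 50.8% of open regions, 31.2% of closed regions and 33.9% of union regions. Another 8 chromosomes (2, 3, 6, 7, 9, 11, 16 and 17) were below the rest (Fisher's exact test, adjusted p at most 0.0215), with shares from 9.0% on chromosome 9 to 14.6% on chromosome 7. The test of each chromosome was added after the lists had been seen.

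**Figure D4:**
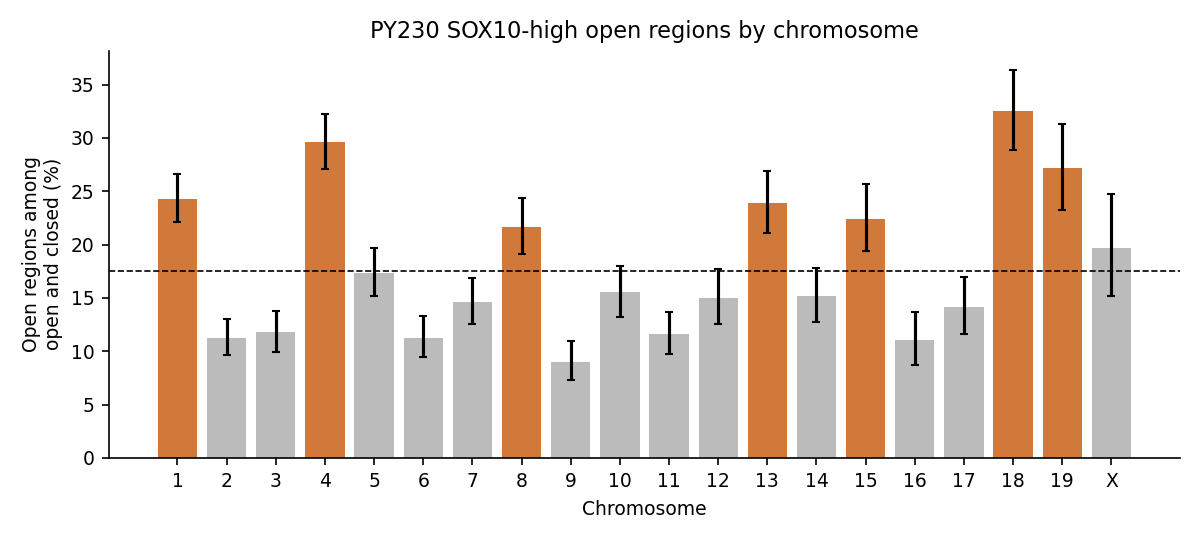
Share of open regions among the open and closed PY230 regions of each chromosome (%, bars with 95% exact binomial intervals). The dashed line is the share over all chromosomes (17.5%), and orange marks the 7 chromosomes with a surplus of open regions at an adjusted p under 0.05.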

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

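Tests of differences between odds ratios and of list length were chosen after the overlaps had been seen, and the test of region edges before its result was seen. The contrast of open with closed PY230 regions differed between cell types. Among PY230 regions overlapping a UAR, the natural log of the odds ratio of being open was 12 for luminal progenitor against mature luminal UARs (95% exact interval 9.53 to 16.2, Fisher's exact test, two-sided, adjusted p = 8.38e-175 over 3 comparisons). For fMaSC against basal UARs it was 3.88 (3.11 to 4.77, Fisher's exact test, adjusted p = 3.53e-40). Luminal progenitor exceeded fMaSC UARs by 2.2 (0.189 to 6.0, Fisher's exact test, adjusted p = 0.0192), a difference that rests on 1 closed region in luminal progenitor UARs and 9 in fMaSC UARs. These tests replaced a normal approximation, which was poor for such small counts and gave the same 3 calls. The value of 12 partly restates that 83.1% of closed regions held a mature luminal peak, which most luminal progenitor UARs lack.

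The size of the mature luminal loss invites a closer look, since 83.1% of all mature luminal UARs lay in the closed list of a tumour line. List length alone is argued against, because the longer basal UAR list was covered to 3.95%. The labels name the closed list with the SOX10-low samples, but whether a mature luminal library also entered the comparison stays open, as mature luminal UARs and closed regions had both edges identical in 3.12% of overlapping pairs against 1.80% of the other list pairs (Fisher's exact test, p = 0.0828), and at least 1 edge identical in 32.8% against 18.5%, looked at afterwards and not tested, while the 34 pairs of fMaSC URRs and closed regions reached 8.82% and 44.1%. Of the 1511 closed regions with the highest score, 90 (5.96%, 4.82 to 7.27%) held no mature luminal peak, which decides nothing, since the share such a library would give is unknown and the bounds tried for it, one from the mature luminal UARs and one of 1%, were set after the value was seen. SOX10-low tumour cells may instead keep much of the mature luminal open chromatin, which is also open and was not tested. The labels tie the closed list to luminal PY230 samples only, and none names a mature luminal library with it.

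Signal outside the comparisons was present on the mitochondrial chromosome, where peaks covered 12285 bases in fMaSC, 12449 in basal cells, 12464 in luminal progenitors and 12473 in mature luminal cells.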

How the results depend on the processing

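The comparisons of UARs with equal numbers of peaks, the Jaccard indices in regions for pairs of types, the draws of URR-sized sets from sites of the other types and the fits without the surplus chromosomes were chosen after seeing the data, and the other alternatives before. No paired analysis was possible because each list combines samples and carries no replicate number. The gene and motif analyses and their alternatives were not run, as no annotation of the build was used. Over 182 comparisons of a result with an alternative, 117 gave the same direction and call, stayed within their interval or, for a count, stayed within 1.5 times the count reported. Two-list tests for fMaSC, luminal progenitor and mature luminal peaks and for fMaSC, luminal progenitor and mature luminal UARs and mature luminal URRs kept their direction and call under each alternative run. Their sizes did not all hold. At 50% overlap the excess in open regions fell from 17.9 to 3.52 points for fMaSC peaks and from 17.2 to 5.53 for luminal progenitor peaks. Mature luminal peaks, in 83.1% of closed regions at 1 bp, lay in 52.1% at 50% overlap and 49.3% with equal numbers. Their shares of open regions fell to 0.343% and 1.34%. The cause was not tested where values moved, except that stricter settings keep fewer peaks. Requiring the median fold left 41357 fMaSC, 41327 basal, 30412 luminal progenitor and 31049 mature luminal peaks. The Jaccard index of luminal progenitor with mature luminal cells was 0.420 at 50% overlap, 0.489 with equal numbers and 0.338 at 500 bp, and that of basal with mature luminal cells 0.280, 0.367 and 0.235. Basal minus luminal progenitor similarity to fMaSC reversed to 0.0199 at 500 bp and 0.0476 in union regions. With equal numbers, 13761 union regions were open in all types, and 5940 in fMaSC, 5926 in basal, 4029 in luminal progenitor and 8432 in mature luminal cells alone. UARs with a peak of another type fell at 50% overlap to 3.36% (fMaSC), 3.58% (basal), 0.654% (luminal progenitor) and 2.86% (mature luminal), and at the median fold to 6.79%, 23.8%, 11.8% and 15.9%. URRs with a peak of their own type (main values 44.2%, 33.8%, 51.9% and 20.6% in the same order) fell to 0%, 0%, 0% and 0.875% (the 0 values allow up to 1.24%, 4.23% and 11.1%), and to 21.1%, 2.82%, 18.5% and 4.86%. The excess of fMaSC UARs with a basal over those with a luminal progenitor peak reversed to -1.31 points at the median fold and -3.11 with equal numbers. That of basal UARs with an fMaSC over a luminal progenitor peak reversed to -1.28 at 50% overlap, and that of luminal progenitor UARs with an fMaSC over a mature luminal peak to -0.98 with equal numbers. Basal peaks became less frequent in open than in closed regions by test at 50% overlap (-5.19 points), with equal numbers (-2.61), at 500 bp (-2.18) and without the 7 surplus chromosomes (-2.62). Without these chromosomes basal UARs also became less frequent in open regions (-0.764). The calls for fMaSC and luminal progenitor URRs were lost inside normal peaks (-0.213 and -0.153) and without those chromosomes (-0.177 and -0.173), where fewer regions were tested. In 500 kb windows the densest windows of luminal progenitor UARs and mature luminal URRs passed (adjusted permutation p = 0.015 and 0.042), which they did not at 1 Mb (0.0899 and 0.418). Depth is unknown, so a site without a peak is not shown to be closed.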

Other observations

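The correlation across chromosomes and the tests of regions outside normal peaks or ordered by fold or score were chosen after the lists had been seen, and the other tests of explanations here before their results were seen. Some PY230 regions overlapped no peak of any normal cell type. Of open regions, 1064 of 3208 (33.2% ± 1.55) lay outside every normal peak, against 2006 of 15108 closed regions (13.3% ± 0.393), and Fisher's exact test gave a two-sided p of 1.7e-143. Of the 321 open regions with the highest score, the share outside was 40.5% (35.1 to 46.1%). Of the 1511 closed regions with the highest score it was 5.76% (4.64 to 7.05%). Mature-luminal-only peaks were closed in SOX10-high cells in 20.8% of the 3646 with the lowest fold and 73.3% of the 3925 with the highest, groups of similar size. Luminal-progenitor-only peaks were open in 5.38% of the 1432 with the lowest fold and 15.7% of the 1456 with the highest. For basal-only peaks the shares were 0.590% of 5427 and 0.563% of 4976.

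The surplus of open regions on 7 chromosomes may reflect a difference in DNA copy number between the compared cells, which ATAC-seq signal would follow. Chromosomes with more open regions per union region had fewer closed regions per union region (Spearman's rho = -0.67, permutation p = 0.00152, adjusted 0.00304; Pearson's r = -0.568, permutation p = 0.0121, and -0.726 without chromosomes X and 18). A greater supply of the cell type combinations that open is argued against. The 7 chromosomes held 1.46 times the union regions in the open list expected from their combinations (1.38 to 1.54). They were chosen for their surplus, which can raise this ratio, and the interval treats regions as independent. Peak width, fold and open regions outside normal peaks did not enter the expectation. A gain would also call sites open in all normal types, but these made up 3.68% of open regions on the 7 chromosomes and 3.36% elsewhere (Fisher's exact test, p = 0.633), which leaves the point undecided. Regional opening linked to SOX10 remains possible and was not tested.

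The scarcity of basal UARs on chromosome X was not explained by weaker or narrower peaks there. Of basal peaks in UARs, 0.536% lay on X, while 1000 draws of basal peaks matched on fold and width gave a median of 1.97% (1.64 to 2.31%). The number of X copies and X inactivation in the sorted cells are possible sources that these lists cannot test.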
